A study of Homo sapiens with 6 samples.

How the data were processed

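Poly(A)-selected RNA from H9-derived lung organoids was sequenced after 48 h with the DPBS vehicle (control), with diesel particulate matter (DPM) or with the ERM-CZ120 reference particles (ERM), with 2 libraries per group and 6 in all. Per the labels, libraries were made with a TruSeq kit from cDNA primed with random hexamers and read as 101-bp pairs to more than 30 M reads each. The deposited table holds 1 FPKM value (fragment count normalized to transcript length and library size) per gene and library for 60676 genes. Per the submitters' processing notes, the authors used cutadapt, Trimmomatic 0.36 and Cufflinks 2.2.1 with the human genome build hg38 (GRCh38), and the aligner, the annotation release and the strand setting are not given in the sources used here. The deposited FPKM values of a library summed to between 800675 and 870946 over all genes, so they were not rescaled to a common total. FPKM from Cufflinks are estimates that divide reads among transcripts and among genes that share sequence, so values of paralogs (the metallothioneins, AKR1C1 with AKR1C2) and of pseudogenes are less certain than those of single-copy genes.

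Values of 1000 FPKM or more carried a comma between digits in the control and DPM columns and none in the ERM columns, and both forms were read as numbers. Each column was assigned to a sample by its name. Gene symbols and Ensembl identifiers are those of the table, and 58503 of the 60676 identifiers were found in GENCODE 29, from which the printed GRCh38 coordinates were taken. They describe whole genes, as the FPKM do.

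Read counts were not recoverable from FPKM with 2 decimals, so the depth per library is known only in relative terms. Among single-exon genes of 480 to 520 nt, the most frequent value above 0, which approximates the worth of 1 fragment, was 0.1 FPKM in control library 1, 0.18 in control library 2, 0.15 and 0.17 in DPM libraries 1 and 2, and 0.14 and 0.21 in ERM libraries 1 and 2. By this measure the deepest library had 2.1 times the depth of the shallowest. Values below 1 FPKM in genes of this length therefore rest on few fragments, and shorter genes need higher values for the same precision.

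Genes with at least 1 FPKM in at least 2 of the 6 libraries were tested, 14995 in all (14547 by the control and DPM libraries alone), on log2(FPKM + 1), so fold changes of genes with low values are understated. One linear model with the 3 groups was fitted with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a mean-variance trend). All groups shared 1 estimate of the spread, with 3 residual degrees of freedom and 3.75 prior degrees of freedom. The tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all tested genes, and the threshold was an adjusted p of 0.05. An adjusted p of a gene comes from this model, unless a fit without a library, another setting or an adjustment over a list alone is named, and log2 changes are given with their standard error (SE). The labels do not say that the 2 samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

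A set of 40 lists of pathway genes and cell type markers was fixed before the data were examined, and the 38 with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01 between genes. The calls were repeated with a correlation estimated for each list and with fry. With an estimated correlation camera takes its p-values from the few residual degrees of freedom of the fit, so a lost call need not come from correlated genes. In DPM vs control the estimate was 0.0094 for the NRF2 list, 0.00065 for the metallothioneins and -0.046 for the AHR list, all below the preset 0.01. It was 0.076 for the WNT and BMP targets and reached 0.845 for the gut and liver markers. The lists for AHR targets, cytochrome P450 genes and metallothioneins follow the title of the series, which names cytochrome P450 and metallothionein, so for these the direction is not independent evidence. Some genes stand on several lists: NQO1 on those of AHR and NRF2, HMOX1, FTL and FTH1 on those of NRF2 and iron handling, and GPX2 on those of NRF2 and the glutathione enzymes. The lists of endothelial and immune cell markers had under 3 tested members and were not tested.

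The rule for named genes was also fixed before the data were examined. In each comparison it takes the 8 largest increases and the 8 largest decreases among genes past the threshold whose groups do not overlap, the 3 members with the largest moderated t from each list called by camera and from the AHR, metallothionein and NRF2 lists, and a fixed set (CYP1A1, CYP1B1, MT1G, MT2A, MT1X, HMOX1, NQO1, NKX2-1, SFTPC, SFTPB, EPCAM and CDH1). Genes named only by a clone or contig were counted and not named, and 2 genes that the rule takes in DPM vs control are not reported here. In the comparisons with ERM the list members are not named, because in 485 rows the ERM values lie far from those of all other libraries, and whether they belong to the genes of these rows is not known. Genes named outside the rule are said to be so.

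For the response shared by DPM and ERM, 100 sets of unchanged groups against the same control libraries were simulated. The fit and the list test were tested on simulated data for DPM vs control, on 14995 genes of which 200 were changed. Of the changed genes, 50.7% were recovered at 1.5-fold, 94% at 2-fold and 100% at 4-fold, and 14 of 177 calls (7.91%) were false. The changed genes were drawn from those with a control mean log2(FPKM + 1) above 2, so the recovery of lower genes is not known. A shifted list was called and a flat list was not. The simulated noise was independent between genes, so this does not test lists of correlated genes. In both simulations the noise of a gene had the spread already moderated by the fit. That spread varies less between genes than the unmoderated one, so recovery in the data may be lower. Alternatives were another pseudocount, 2 other filters, median-of-ratios scaling, quantile normalization, the replicate number as a block, no variance trend, only the 2 groups compared, each library left out in turn, a minimum fold change and, chosen after the data were seen, a separate control library for each particle in the shared response. Figures were drawn with matplotlib 3.10.9.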

Results

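Lung organoids were grown from H9, an established human embryonic stem cell line, by way of definitive endoderm and ventralized anterior foregut, in Matrigel and in medium with the GSK3 inhibitor CHIR99021, BMP4, FGF7, FGF10 and retinoic acid. They were exposed for 48 h to DPM (NIST SRM 1650b, a reference diesel particulate matter) or to ERM (ERM-CZ120, an environmental particle reference material), at doses that the labels describe only as sub-lethal. Control organoids received the DPBS vehicle. The study asked how the transcriptome of these organoids responds to each particle, and its title names cytochrome P450 and metallothionein genes. RNA-seq gave FPKM for 2 libraries per group. The 2 control libraries correlated over genes at r = 0.987, the 2 DPM libraries at 0.984 and the 2 ERM libraries at 0.985, on the log2(FPKM + 1) scale. Control and DPM libraries correlated at 0.963 or more with each other, whereas an ERM library and any other correlated at 0.764 to 0.774. Between 14247 and 14454 genes had at least 1 FPKM per library. Relative depth, read from the smallest steps in the values, differed up to 2.1-fold, with control library 1 the deepest and ERM library 2 the shallowest. In 485 rows the ERM values lay more than 8-fold from all 4 other libraries, and they may not belong to the genes of these rows. The account of single genes therefore rests on the changes between DPM and control. The ERM libraries still entered the filter and the spread behind the adjusted p-values of DPM vs control. This holds also for genes among the 485 rows, such as FTL, RPL23, RPLP1 and RPS6. Of the 1531 genes that passed in this fit, 1425 also passed when only control and DPM were fitted.

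The organoids expressed EPCAM and CDH1 at high levels and NKX2-1 and the surfactant protein genes SFTPB and SFTPC below 1 FPKM, while 16 of the 18 lung progenitor markers and 15 of the 17 gut and liver markers on the fixed lists passed the filter. Passing needs only 1 FPKM in 2 of the 6 libraries, so these counts do not compare levels. The gut and liver markers VIL1 and TTR had control means of 87.0 and 65.0 FPKM, and LGALS4, named after its values were seen, 3.92. EPCAM, an epithelial adhesion protein, stood at 493 ± 46.1 FPKM (SD, n = 2) in control and 496 ± 1.41 with DPM, and CDH1, which encodes E-cadherin, at 142 ± 12.5 and 151 ± 8.68. Their log2 differences, 0.01 (SE 0.09) and 0.09 (SE 0.10), did not pass the threshold (adjusted p = 0.949 and 0.562), and both turned just below 0 with median-of-ratios scaling (-0.080 and -0.0011). NKX2-1, the transcription factor that marks lung endoderm, lay between 0.15 and 0.68 FPKM over the 4 control and DPM libraries. SFTPB, a surfactant protein gene, reached at most 0.42 FPKM in them, and SFTPC, another, was listed at 0 in all 6 libraries. These 3 genes were below the filter and were not tested. Without read counts a listed 0 need not mean that a gene was silent. CAT, the catalase gene, named after its values were seen, was also listed at 0 in the DPM and ERM libraries and at 0.03 and 0.05 FPKM in control.

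With DPM, target genes of the aryl hydrocarbon receptor (AHR), which senses polycyclic aromatic compounds, rose. CYP1A1, an AHR-induced monooxygenase (ENSG00000140465, chromosome 15 of GRCh38, 74719542 to 74725610, minus strand), stood at 45.2 and 30.6 FPKM in the control libraries and at 769 and 518 with DPM, 17.0-fold higher by the means (log2 change 4.05, SE 0.23, adjusted p = 0.000493). CYP1B1, its relative (ENSG00000138061, chromosome 2, 38066973 to 38109902, minus strand), rose from 8.96 ± 0.163 to 139 ± 19.4 FPKM (log2 change 3.81, SE 0.13, adjusted p = 8.52e-05). TIPARP, an AHR target that feeds back on the receptor, rose from 14.2 ± 1.05 to 40.7 ± 1.56 FPKM (log2 change 1.46). Of the 9 tested members of the list, 5 rose and none fell, or 6 when adjusted over the list alone, with a median log2 change of 1.12. CYP1A2, named after its values were seen, was tested only because of its ERM values, and when only control and DPM were fitted 6 of 8 rose. This list and that of the metallothioneins follow the series title, so their direction is not independent evidence. Camera called the list at an adjusted p of 1.01e-05. With an estimated correlation the call was lost (adjusted p = 0.147), while over the 15 settings with the preset correlation it stayed between 4.3e-07 and 0.00012. Of the 15 tested cytochrome P450 genes outside the CYP1 family, or 14 when only control and DPM were fitted, 1 rose, and that list was not called (adjusted p = 0.534).

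Metallothionein genes, which encode small metal-binding proteins, also rose with DPM. They lie together on chromosome 16, from the start of MT2A at 56608199 to the end of MT1X at 56684196. MT1G increased from 1.38 ± 0.00707 to 16.5 ± 3.80 FPKM (log2 change 2.86, SE 0.16, adjusted p = 0.000451), MT2A from 6.81 ± 1.39 to 55.3 ± 4.48 (log2 change 2.86), MT1E from 0.91 ± 0.0424 to 8.62 ± 1.29 (log2 change 2.33) and MT1X from 14.4 ± 1.22 to 56.3 ± 6.56 (log2 change 1.89, adjusted p = 0.00126). Of the 6 tested members 5 rose, and all 6 when adjusted over the list alone, with a median log2 change of 2.24. The list was called at an adjusted p of 3.73e-07 (5.27e-09 to 8.43e-05 over the 15 settings with the preset correlation) and lost the call with an estimated correlation (adjusted p = 0.144). These genes are near-identical paralogs, so the division of reads among them is uncertain.

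**Figure D1:**
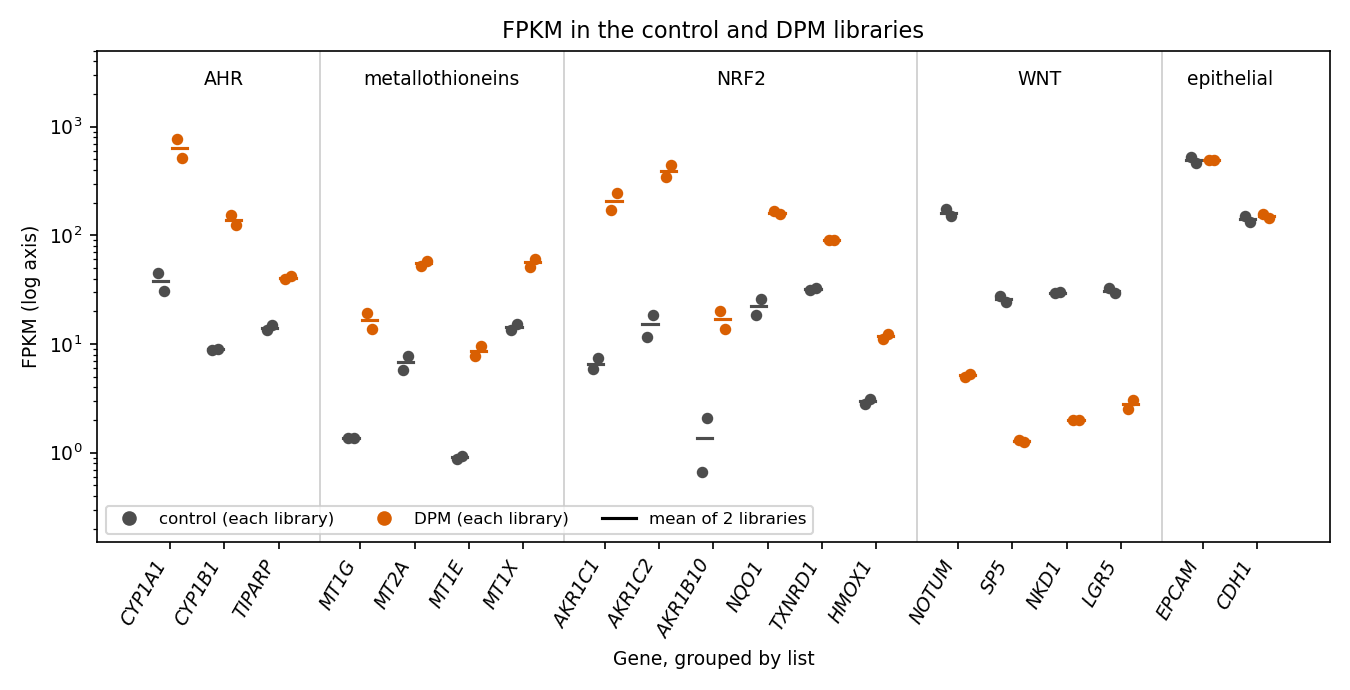
FPKM on a log axis of genes named by the fixed rule, with grey points for the 2 control libraries, orange points for the 2 DPM libraries and a horizontal bar at the mean of 2 libraries. CYP1A1 goes from a mean of 37.9 to 643 FPKM and NOTUM from 162 to 5.17 FPKM, while the points of EPCAM and CDH1 lie close together.

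Targets of NRF2, the transcription factor of the oxidative and electrophile stress response, were the largest group of genes to rise. AKR1C1 and AKR1C2, aldo-keto reductases that lie side by side on chromosome 10 (4963253 to 4983283 and 4987400 to 5018031), showed the 2 largest increases among named genes: AKR1C1 from 6.62 ± 1.07 to 209 ± 52.5 FPKM (log2 change 4.77, SE 0.18, adjusted p = 0.000103) and AKR1C2 from 15.1 ± 5.01 to 394 ± 73.7 (log2 change 4.64). Reads can be shared between these paralogs. AKR1B10, a further aldo-keto reductase, rose by a log2 change of 2.96 (SE 0.31), NQO1, a quinone reductase, by 2.83 (SE 0.19), from 22.2 ± 5.41 to 162 ± 7.01 FPKM, TXNRD1, the cytosolic thioredoxin reductase, by 1.47 (SE 0.09), and HMOX1, heme oxygenase 1, by 1.68 (SE 0.13), from 2.96 ± 0.184 to 11.7 ± 0.940 FPKM. In the NRF2 list 20 of 27 genes rose and none fell, while 22 rose and 1 fell when adjusted over the list alone, with a median log2 change of 1.28. Its camera call (adjusted p = 1.58e-14, and 2.07e-17 to 6.62e-13 over the 15 settings with the preset correlation) was lost with an estimated correlation (adjusted p = 0.129).

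The lists of glutathione enzymes and iron genes overlap with the NRF2 list, which holds GPX2, HMOX1, FTL and FTH1, and most of their members did not pass the threshold. GPX2, a glutathione peroxidase, rose by a log2 change of 2.16 (SE 0.20), MGST1 by 0.56 (SE 0.08) and GSTM3 by 0.51 (SE 0.09). Of 22 glutathione S-transferases and peroxidases, 5 rose, or 12 when adjusted over the list alone (camera adjusted p = 0.00178, and adjusted p = 0.538 with an estimated correlation). FTL and FTH1, the ferritin light and heavy chains, rose by log2 changes of 1.28 (SE 0.12) and 0.68 (SE 0.11), to 7035 ± 559 and 1717 ± 252 FPKM. Of 11 iron handling genes 4 rose, or 5 when adjusted over the list alone (camera adjusted p = 0.00568, and adjusted p = 0.289 with an estimated correlation). MGST1 lost its call without control library 1, control library 2 or DPM library 1 (adjusted p = 0.063 to 0.0901), GSTM3 without any 1 of the 4 control and DPM libraries (0.0768 to 0.136) and FTH1 without either control library (0.0928 and 0.112). KCNA5, a voltage-gated potassium channel, was also among the 8 largest increases. It rose from 0.63 ± 0.0283 to 14.8 ± 4.99 FPKM (log2 change 3.24, SE 0.24).

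Genes of the WNT pathway fell with DPM. NOTUM, a secreted WNT-inactivating enzyme and itself a WNT target, (ENSG00000185269, chromosome 17, 81952507 to 81961840, minus strand), fell from 162 ± 15.7 to 5.17 ± 0.247 FPKM, 31.3-fold lower by the means (log2 change -4.72, SE 0.14, adjusted p = 7.99e-05). SP5, a transcription factor induced by WNT, went from 27.6 and 24.5 to 1.30 and 1.26 FPKM (log2 change -3.56), NKD1, an inhibitor of the pathway, from 29.8 ± 0.0495 to 2.00 ± 0.0212 (log2 change -3.36), and LGR5, a receptor for R-spondins, from 31.0 ± 2.52 to 2.79 ± 0.346 (log2 change -3.08, SE 0.11). Of the 15 WNT and BMP targets 12 fell and none rose, or 13 when adjusted over the list alone, with a median log2 change of -1.27. The camera call at an adjusted p of 1.02e-17 (1.4e-18 to 3.67e-14 over the 15 settings with the preset correlation) was lost with an estimated correlation (adjusted p = 0.129).

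The other large decreases belonged to no list. PCP4, which encodes a calmodulin-binding peptide, fell from 69.7 ± 7.13 to 5.70 ± 1.12 FPKM (log2 change -3.41, SE 0.17, adjusted p = 0.000303). RPL39P3, a ribosomal protein pseudogene, went from 25.2 and 22.4 FPKM to values listed at 0 in both DPM libraries (adjusted p = 7.99e-05), and its reads can be shared with its parent gene. MYH7B, a myosin heavy chain gene, stood at 9.77 and 14.4 FPKM in control and at 0.09 and 0.32 with DPM (log2 change -3.42, SE 0.51, adjusted p = 0.0144). NOX3, an NADPH oxidase gene, stood at 12.9 and 6.66 against 0.2 and 0.73 (log2 change -2.84, SE 0.39, adjusted p = 0.012). The call of MYH7B was lost without control library 1, control library 2 or DPM library 1 (adjusted p = 0.0592 to 0.0924), and that of NOX3 without control library 1 or DPM library 1 (0.06 and 0.0643).

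Camera called the cytosolic ribosomal proteins, the cell cycle genes and the hypoxia and glycolysis genes lower, with a minority of members past the threshold, and fry called the ribosomal proteins but neither the cell cycle (adjusted p = 0.111) nor the hypoxia and glycolysis genes (adjusted p = 0.315). Of the 30 genes for cytosolic ribosomal proteins 9 fell and none rose, or 27 when adjusted over the list alone, with a median log2 change of -0.37. RPL23 fell from 3915 ± 192 to 2908 ± 150 FPKM (log2 change -0.43), RPLP1 by 0.60 on the log2 scale and RPS6 by 0.37. Camera called this list at an adjusted p of 3.79e-15, and the call was lost with an estimated correlation (adjusted p = 0.289) and with quantile normalization (adjusted p = 0.0721, median -0.09). Among 27 cell cycle genes 5 fell, or 15 when adjusted over the list alone, with a median of -0.39 (camera adjusted p = 1.31e-11, and adjusted p = 0.538 with an estimated correlation). CENPF, a kinetochore protein, fell by 0.83, TOP2A, topoisomerase II alpha, by 0.62 and BUB1, a spindle checkpoint kinase, by 0.59. Of 21 hypoxia and glycolysis genes 2 fell, or 3 when adjusted over the list alone, PFKFB3 by 0.80 and CA9, carbonic anhydrase 9, by 0.78, and ANKRD37, at -1.37, had an adjusted p of 0.0543 (camera adjusted p = 4.57e-05, and adjusted p = 0.672 with an estimated correlation). When only control and DPM were fitted, 16 ribosomal protein genes and 10 cell cycle genes fell, and of the hypoxia and glycolysis genes 5 fell and 1 rose. RPL23, RPLP1, RPS6, BUB1 and CA9 lost their calls without any 1 of the 4 control and DPM libraries (adjusted p = 0.0524 to 0.221), CENPF and TOP2A without control library 1, control library 2 or DPM library 1 (0.0978 to 0.155) and PFKFB3 without control library 2 or DPM library 1 (0.0707 and 0.055).

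Camera also called lists of cell type markers, each with 1 to 3 single members past the threshold, and the retinoic acid genes, with 6 of 11. Fry called the retinoic acid genes (adjusted p = 0.00362) and none of the 5 marker lists: mesenchymal (0.213), epithelial-mesenchymal transition (0.317), neural (0.109), ciliated (0.107), and gut and liver (0.317). Of 10 mesenchymal markers 2 fell, DCN (decorin) by 1.84 and LUM (lumican) by 0.83 on the log2 scale, while COL1A1 stood at 0.62 (adjusted p = 0.085). Adjusted over the list alone, 2 fell and 1 rose (camera adjusted p = 0.00513, and adjusted p = 0.634 with an estimated correlation). Of 13 genes of the epithelial-mesenchymal transition 3 fell, also when adjusted over the list alone. VIM, which encodes vimentin, fell by 1.07, from 608 ± 105 to 287 ± 14.5 FPKM, and the transcription factors TWIST1 and SNAI1 by 1.36 and 0.99 (camera adjusted p = 0.0327, and adjusted p = 0.672 with an estimated correlation). Control library 2 also held muscle genes that the other control library and the DPM libraries lacked, such as MYOG, chosen after its values were seen, at 8.17 FPKM against 0 in each of those 3. Without control library 2 neither the mesenchymal list (adjusted p = 0.207) nor the epithelial-mesenchymal transition list (adjusted p = 0.394) was called. Their medians were then -0.18 and -0.02, against -0.50 and -0.53 with all libraries, while over the 4 fits without a control or DPM library DCN stayed between -2.19 and -1.49, VIM between -1.25 and -0.89 and TWIST1 below -1. The epithelial-mesenchymal transition list was called in 5 of the 15 settings (adjusted p = 0.102 when only control and DPM were fitted, and 0.096 with median-of-ratios scaling). The mesenchymal list was also not called among genes with a mean of at least 5 FPKM (adjusted p = 0.069). DCN lost its call without control library 2 or DPM library 1 (adjusted p = 0.0824 and 0.0555), LUM without control library 1, control library 2 or DPM library 1 (0.0556 to 0.0997), VIM without any 1 of the 4 control and DPM libraries (0.0556 to 0.12), and TWIST1 and SNAI1 without control library 2 or either DPM library (0.0678 to 0.169).

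Among 7 neural markers NCAM1, a neural cell adhesion molecule, fell by 1.32, and GAP43 (-1.23) and ELAVL4 (-0.88) did not pass the threshold (adjusted p = 0.0707 and 0.083). Adjusted over the list alone, 5 neural markers fell (camera adjusted p = 0.00282, and adjusted p = 0.538 with an estimated correlation). Of 10 ciliated cell markers 2 fell, FOXJ1, the master regulator of motile cilia, by 1.16, from 11.2 ± 1.61 to 4.45 ± 0.672 FPKM, and PIFO by 0.49, while TPPP3 stood at -1.76 (adjusted p = 0.0501). Adjusted over the list alone, 4 fell and 1 rose (camera adjusted p = 0.0327, and adjusted p = 0.538 with an estimated correlation). When only control and DPM were fitted, 4 of 9 ciliated cell markers fell, and TPPP3 passed the threshold (adjusted p = 0.0145). Of 11 retinoic acid genes 5 fell and 1 rose, or 6 and 3 when adjusted over the list alone. STRA6, a retinol transporter, fell by 0.97, whereas ALDH1A1, a retinaldehyde dehydrogenase, rose by 2.11, from 34.9 ± 4.41 to 157 ± 44.5 FPKM (camera adjusted p = 0.0151, and adjusted p = 0.33 with an estimated correlation). Of 15 gut and liver markers, TTR (transthyretin) rose by 1.65, and VIL1 (0.64) and HNF4A (1.04) did not pass the threshold (adjusted p = 0.0598 and 0.0721). Adjusted over the list alone, 6 rose (camera adjusted p = 0.0141, and adjusted p = 0.755 with an estimated correlation). The call of the gut and liver markers was lost without DPM library 1 (adjusted p = 0.424), and without DPM library 2 it rested on 8 genes that rose (adjusted p = 5.43e-09). TTR lost its call without either control library (adjusted p = 0.0653 and 0.0784), FOXJ1 without control library 1 (0.0615), the ciliated cell markers as a list without DPM library 1 (0.163), with median-of-ratios scaling (0.0855) and with quantile normalization (0.0721), the neural markers as a list among genes with a mean of at least 5 FPKM (0.0697), and PIFO without control library 1, control library 2 or DPM library 1 (0.0978 to 0.152).

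**Figure D2:**
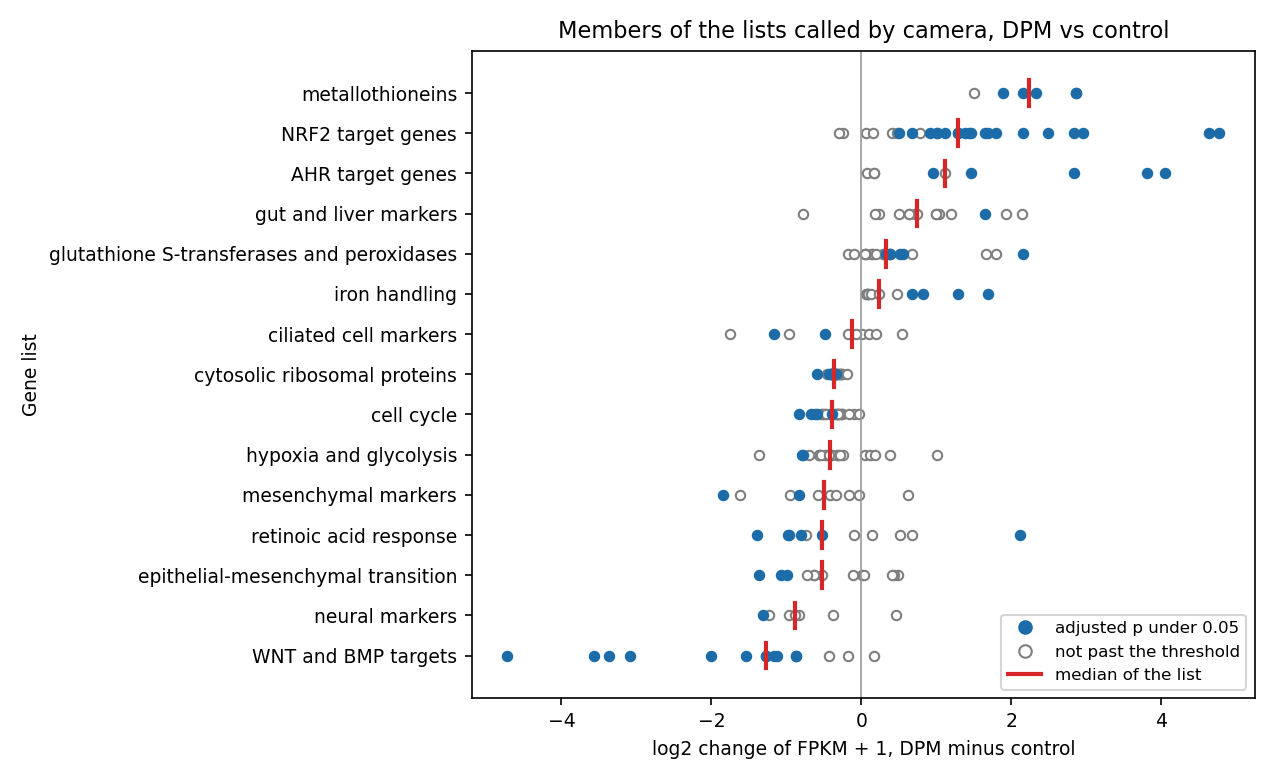
Log2 change of FPKM + 1 (DPM minus control) of each tested member of the 15 lists that camera called, with filled points for genes at an adjusted p under 0.05, open points for the others and a red bar at the median of the list. The medians run from -1.27 for the WNT and BMP targets to 2.24 for the metallothioneins.

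In all, 1531 of 14995 genes changed with DPM, 1012 higher and 519 lower, and 371 of them by a log2 change of at least 1 (197 higher and 174 lower). The balance of directions depended on the scaling: 594 genes were higher and 710 lower with median-of-ratios scaling, and 583 higher and 633 lower with quantile normalization. With no filter beyond values above 0, 431 genes passed. Without the ERM libraries in the fit, 1750 genes passed, of which 1425 were among the 1531. The count fell to 263 without control library 1, 229 without control library 2, 309 without DPM library 1 and 744 without DPM library 2, where the lone library of a group is assumed to vary like the others. Camera called 15 of 38 lists, 6 up and 9 down, fry called 12, and with an estimated correlation 0 were called by camera (lowest adjusted p 0.129, with 6 lists at an unadjusted p under 0.05). The estimated correlations of the NRF2, metallothionein and AHR lists lay below the preset 0.01, so their lost calls do not show correlated genes.

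The comparison of ERM with control passed 1359 of 14995 genes, 712 higher and 647 lower, but it cannot be read gene by gene. In both ERM libraries KLHL40, PTCHD1, MUC17, KIF26B, ALPP, RAPSN, CYP2C19 and AKNAD1 stood at 2544 FPKM or more, against at most 0.98 FPKM in either control library. RPL17, FTL, ENO1, RPLP0, RPS12, MT-ND4L, RPL31 and RPS19 stood at 0.13 to 5.49 FPKM in ERM, against 2103 to 5556 in control. These are the 8 largest increases and the 8 largest decreases, with log2 changes up to 11.94 and down to -11.98. GAPDH, chosen after its values were seen, had 7.38 and 7.76 FPKM in the ERM libraries, 4595 and 5288 in control and 3734 and 3451 with DPM. In ERM, KLHL40, a muscle gene, thus stood at the level that ribosomal protein genes had in control, and ENO1, a glycolytic enzyme gene, near 0.

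Such values filled part of the table. In 485 rows both ERM libraries lay more than 8-fold from all 4 other libraries, 246 higher and 239 lower, a limit set after the data were seen. By the same measure, a difference of more than 3 on the log2(FPKM + 1) scale, DPM lay apart from both controls in 5 rows upward and 7 downward. Of 124 genes with a control mean of 1000 FPKM or more, 79 had an ERM mean under 100 FPKM, and in the other direction 72 of 119 genes with an ERM mean of 1000 FPKM or more had a control mean under 100 FPKM. Of the 30 cytosolic ribosomal protein genes 24 were more than 8-fold lower in ERM and 6 within 2-fold of control. Among 5945 genes with a mean log2(FPKM + 1) of at least 4 in the control and DPM libraries, ERM lay within 2-fold in 90.1%, and DPM lay over 2-fold from control in 1.98%. All 485 rows were among the 1359 calls, and 88.8% of the calls were at least 2-fold, against 24.2% with DPM.

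**Figure D3:**
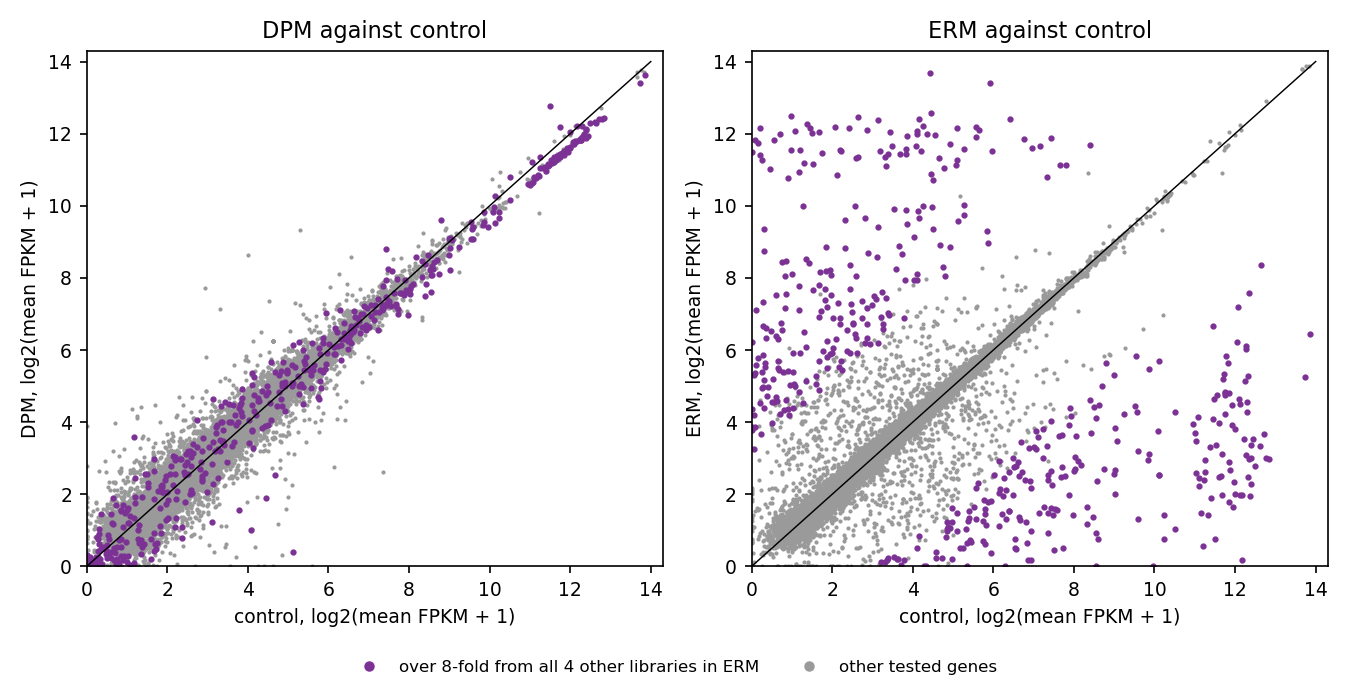
Mean FPKM of DPM (left) and ERM (right) against control on the log2(FPKM + 1) scale, one point per tested gene, with the line of equality. Purple points are the 485 rows in which both ERM libraries lie over 8-fold from all 4 other libraries. They lie far off the line in the ERM panel and near it in the DPM panel.

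For the genes that the study's title and the fixed set point to, the ERM columns gave the values that follow, and whether each row holds its own gene cannot be told from the table. CYP1A1 stood at 31.8 ± 1.15 FPKM against 37.9 ± 10.3 in control (log2 change -0.22, SE 0.23, adjusted p = 0.746) and CYP1B1 at 8.56 ± 1.03 against 8.96 ± 0.163 (-0.06, SE 0.13, adjusted p = 0.879). MT1X stood at 12.6 ± 1.48 against 14.4 ± 1.22 (-0.19, adjusted p = 0.616), MT2A at 12.8 ± 0.474 against 6.81 ± 1.39 (0.83, adjusted p = 0.00866) and MT1G at 24.3 ± 1.09 against 1.38 ± 0.00707 (3.41, adjusted p = 5.08e-06). HMOX1 stood at 27.1 ± 3.79 against 2.96 ± 0.184 (2.82, adjusted p = 5.19e-06) and NQO1 at 6.31 ± 1.39 against 22.2 ± 5.41 (-1.66, adjusted p = 0.000904). EPCAM (-0.04) and CDH1 (0.02) did not pass the threshold (adjusted p = 0.887 and 0.946). Camera called 9 lists, 2 up and 7 down, led by the cytosolic ribosomal proteins (25 of 30 lower). The others were the integrated stress response, heat shock proteins, mitochondrially encoded genes, retinoic acid genes, p53 targets and WNT and BMP targets, all lower, and NF-kB and cytokine genes and immediate early genes, both higher. For the mitochondrially encoded genes, 4 of 13 lower, the median of 0.12 was above 0. Camera called 0 lists with an estimated correlation (lowest adjusted p 0.301, 1 list at an unadjusted p under 0.05). Fry called 21. Camera called neither the AHR targets (2 higher and 2 lower of 9, adjusted p = 0.691) nor the metallothioneins (3 of 6 higher, adjusted p = 0.0601) nor the NRF2 targets (3 higher and 6 lower of 27, adjusted p = 0.396). When only ERM and control were fitted, it called the metallothioneins (4 of 6 higher, adjusted p = 0.0383). Fry called the AHR targets (adjusted p = 0.0101) and the metallothioneins (0.00156) higher and the NRF2 targets (0.00174) lower.

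The comparison of DPM with ERM carries the same limit. It passed 2202 of 14995 genes, 1180 higher and 1022 lower with DPM, and 1349 of these by a log2 change of at least 1. The 16 largest changes all lay among the 485 rows: FTL, RPL17, ENO1, MT-ND4L, RPLP0, RPS12, RPL31 and RPS19 higher with DPM, by log2 changes from 9.81 to 12.02, and KLHL40, KIF26B, PTCHD1, FGF18, MUC17, RAPSN, INHBB and AKNAD1 lower, from -12.11 to -11.33. With the same limit on the ERM values, CYP1A1 was higher with DPM than with ERM by a log2 change of 4.27, CYP1B1 by 3.87, NQO1 by 4.49, MT1X by 2.08 and MT2A by 2.03, while HMOX1 was lower (-1.14, adjusted p = 0.000937) and MT1G (-0.55) did not pass the threshold (adjusted p = 0.0672). EPCAM and CDH1 differed by 0.05 and 0.07 (adjusted p = 0.754 and 0.699). Camera called 11 lists, 7 higher and 4 lower with DPM, fry called 24, and with an estimated correlation 0 were called (lowest adjusted p 0.226, 3 lists at an unadjusted p under 0.05).

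Changes with DPM and with ERM were weakly related across genes, which are not independent replicates. The Pearson correlation of the 2 sets of log2 changes was 0.144 over 14995 genes (Spearman 0.375), and the covariance was 0.0797 against a simulated 0.0172. Unchanged groups that share the control libraries gave a simulated mean correlation of 0.498 (SD 0.0159). That correlation comes from the shared libraries alone. Large changes in either group add variance and can lower the correlation, so 0.144 cannot be read against it. In both comparisons 249 genes passed in the same direction, 152 higher and 97 lower, and 151 in opposite directions. The ERM values of the 485 rows enter all these numbers, and 77 of the 249 genes (37 higher and 40 lower) and 49 of the 151 are among these rows. The simulation, in which no gene was changed, gave a mean of 0.08 genes in the same direction, and independent lists of the observed sizes would share 48.1 higher and 22.4 lower. The same-direction count fell to 78 without control library 1, 73 without control library 2 and 80 without DPM library 1. With each particle compared with its own control library, an alternative chosen after the data were seen, 58 or 66 genes passed in the same direction and 39 or 61 in opposite directions, depending on which library served which particle, and the covariance was 0.0661 or 0.0445. Independent lists of those sizes would share 4.95 higher and 3.79 lower, or 4.84 higher and 5.14 lower. No such number was computed for opposite directions, neither here nor for the 151 genes above. The counts therefore do not show that the overlap favours the same direction. Each of these fits rests on 1 control library per comparison, assumed to vary like the other groups.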

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

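The alternatives reported here were chosen before the data were examined, except the separate control libraries of the shared count. For DPM vs control the count of 1531 genes lay between 1052 and 1750 with a pseudocount of 0.1 (1470), a mean of at least 5 FPKM (1457), both scalings (1304 and 1216), no variance trend (1172), the replicate block (1052), only the 2 groups (1750) and either ERM library left out (1623 and 1634). It moved further with no filter beyond values above 0 (431, where 25976 genes were tested), with a log2 change of at least 1 (371, by construction a subset), and without a control or DPM library (229 to 744), where fewer libraries remain. The ERM vs control count of 1359 lay between 1239 and 1388 without 1 library. The DPM vs ERM count of 2202 became 1349 with a log2 change of at least 1 and 1694 to 1865 without 1 library. The shared count of 249 became 103 with no filter and 73 to 255 without 1 library, and 58 or 66 with a separate control library for each particle, where fewer libraries stand behind each comparison. With an estimated correlation 0 lists were called in each comparison, and fry, which asks another question, called 21 lists against 9 for ERM vs control and 24 against 11 for DPM vs ERM. The causes of the other moves were not tested.

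Of 55 named genes called in DPM vs control, 27 kept the call in all 4 fits without a control or DPM library, 27 lost it in at least 1, and RPL39P3 was not tested without either control library. Over all comparisons, 119 pairs of a named gene and a comparison gave 12 changes of sign, 117 lost calls (21 of them with no filter) and 20 gained calls, against 1485 refits with neither. The changes of sign were all in values that had not passed the threshold. In DPM vs control they were CDH1 (-0.0011) and EPCAM (-0.080) with median-of-ratios scaling, EPCAM without control library 2 (-0.084 to 0.107 over the fits without 1 library) and AFP without DPM library 1 (-0.188 to 1.60). In ERM vs control they were CDH1 with median-of-ratios scaling (-0.024), without control library 2 and without ERM library 2 (-0.066 to 0.113), EPCAM with quantile normalization (0.024) and without control library 1 (-0.137 to 0.054), CYP1B1 without ERM library 2 (-0.173 to 0.046) and CYP1A1 without control library 1 (-0.494 to 0.055). In DPM vs ERM it was EPCAM with quantile normalization (-0.013).

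The replicate numbers do not show that samples were paired. The differences of library 1 minus library 2 correlated over genes at -0.047 between control and DPM, 0.005 between control and ERM and 0.046 between DPM and ERM. With the replicate number as a block, 1052, 1330 and 2037 genes passed in the 3 comparisons. A count test was not run, because read counts are not recoverable from FPKM with 2 decimals. Absolute depth is not known. Values below 1 FPKM can rest on few fragments, and the pseudocount of 1 FPKM shrinks their differences, so small differences in such genes were not detectable here.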

Other observations

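The tests of the ERM rows and of the mesenchymal share were chosen after the result was seen, whereas the test of scaling and the test on the muscle list were set before theirs. Genes named in the 2 paragraphs that follow, and the muscle genes named below, were chosen after their values were seen.

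Camera called none of the NF-kB, p53, unfolded protein response, heat shock and zinc transporter lists with DPM. None of 14 tested NF-kB and cytokine genes passed the limma threshold (12 when only control and DPM were fitted, as CXCL2 and IL33 passed the filter by their ERM values), although 4 had an unadjusted p under 0.05, with 0 also when adjusted over the list alone and with the list not called (adjusted p = 0.636, and fry adjusted p = 0.315). CXCL8, which encodes interleukin 8, stood at 0.42 and 0.69 FPKM in control and 1.51 and 1.08 with DPM (adjusted p = 0.075), and CCL2 at 5.03 and 9.9 against 2.32 and 4.47 (adjusted p = 0.243). Of 18 p53 targets 1 rose and 1 fell, and of 16 genes of the unfolded protein response 1 rose. Of 13 heat shock genes 4 rose and 1 fell (list adjusted p = 0.235, 0.0417 to 0.471 over the 15 settings with the preset correlation, and fry adjusted p = 0.0821). Among them BAG3 rose by 0.69 and HSPA1B by 0.58 on the log2 scale, and both lost their calls without any 1 of the 4 control and DPM libraries (adjusted p = 0.0512 to 0.145). Of 16 zinc transporter genes with MTF1, the metal-sensing factor that induces metallothioneins, SLC30A1 alone passed (2 of 15 when only control and DPM were fitted), and fry called the list (adjusted p = 0.0207) where camera did not (0.204). This zinc exporter rose from 15.8 ± 0.177 to 38.4 ± 2.11 FPKM (SD, n = 2, log2 change 1.23, adjusted p = 0.00205).

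Lung progenitor markers moved in both directions with DPM, with 3 of 16 higher and 4 lower (list adjusted p = 0.0515). Over the 15 settings with the preset correlation that adjusted p ran from 0.0276 to 0.203, and camera called the list lower in 6 of them. IRX3, a homeobox gene, fell from 23.2 ± 1.20 to 5.67 ± 0.332 FPKM (log2 change -1.86, adjusted p = 0.000417), BMP4 fell by 1.13 and GATA6, an endoderm transcription factor, rose by 0.76. BMP4 lost its call without control library 2 or either DPM library (adjusted p = 0.0529 to 0.08) and GATA6 without control library 2 or DPM library 1 (0.0784 and 0.0562). Among 10 coronavirus entry factors, FURIN rose by 0.78 and TMPRSS4 by 0.61, with the list not called (adjusted p = 0.715). FURIN lost its call without control library 1, control library 2 or DPM library 1 (adjusted p = 0.0515 to 0.117), and TMPRSS4 without any 1 of the 4 (0.0526 to 0.164). The gut and liver markers differed between the 2 DPM libraries. FABP1 stood at 581 and 190 FPKM in DPM libraries 1 and 2 against 60.1 and 126 in control, LGALS4 at 40.5 and 9.05 against 2.27 and 5.57, and AFP at 261 and 74.6 against 88.1 and 82.1. Camera did not call the other tested lists in DPM vs control, and fry called 3 of them, the airway secretory markers (adjusted p = 0.00399), the interferon-stimulated genes and the alveolar type 1 markers (adjusted p = 0.0459 for both). Their members past the threshold were: immediate early genes (2 of 13 higher), pan-epithelial markers (2 of 15 higher), interferon-stimulated genes (1 higher and 3 lower of 15), oxidative phosphorylation (1 of 26 lower), the integrated stress response (1 of 17 lower), alveolar type 1 markers (2 of 9 higher), alveolar type 2 markers (1 of 6 lower), cholesterol biosynthesis (1 of 21 higher), airway secretory markers (2 higher and 1 lower of 8), airway basal markers (1 higher and 1 lower of 5), housekeeping genes (1 of 12 lower), extracellular matrix and fibrosis (1 of 23 higher), mitochondrially encoded genes (0 of 13 by limma, 1 at an unadjusted p under 0.05), neuroendocrine markers (0 of 6, and 1 likewise) and pluripotency markers (1 of 8 higher). The counts adjusted over the list alone differed for lung progenitor markers (3 higher and 7 lower), immediate early genes (5 and 1), zinc transporters (6 and 0), heat shock proteins (5 and 1), the integrated stress response (0 and 2), alveolar type 1 (4 and 1) and type 2 markers (1 and 1), cholesterol biosynthesis (0 and 0), airway secretory markers (3 and 1), coronavirus entry factors (2 and 1) and pluripotency markers (2 and 0). Camera leaned down while the median was above 0 for housekeeping genes, p53 targets, neuroendocrine and alveolar type 2 markers, and while the mean was above 0 for cholesterol biosynthesis.

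In 485 rows the ERM values lie far from the other 4 libraries, and 26.0% of these rows were called in DPM vs control, against 9.68% of the other tested rows. A response of the organoids is argued against by the cytosolic ribosomal protein genes, whose log2 changes had an SD of 3.44 with ERM against 0.072 with DPM, because 24 fell more than 8-fold and 6 stayed within 2-fold. Reads shared with pseudogenes are argued against too, since 3 of the 246 far higher rows (1.22%) are pseudogenes. That values were placed in the rows of other genes stays open as a hypothesis: the ERM and control values of the 485 rows, each sorted by size, differed by a median of 0.199 on the log2 scale, but rows chosen for large differences in both directions can bring the sorted values close under other causes too, so this does not decide. Neighbouring rows among the 485 had similar ERM levels (rank correlation 0.692, against 0.165 for the control and DPM levels), and how values would have to be put back is not known from the table, so none was moved.

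The WNT and BMP targets fell with DPM in organoids kept in ventralization medium, which per the labels contains CHIR99021, an activator of WNT signalling (the medium during the 48 h of exposure is not given separately). Library scaling as the whole cause is argued against by the size of the fall, because a scaling factor moves all genes of a library about alike. The median log2 change was 0.0764 over all tested genes and -1.27 over the list. With median-of-ratios scaling 13 members of the list were called lower. That test had little room to come out otherwise, so it adds no support. A lower share of mesenchymal cells stays open: the median log2 change of the 10 mesenchymal markers, -0.50 (SD 0.734), lies 0.778 above that of the 15 WNT and BMP targets (one-sided permutation p = 0.0251 over 100000 resamples of genes, which are not independent replicates), but only 0.202 above it without control library 1. The difference was 1.18 without control library 2, 0.721 without DPM library 1 and 0.679 without DPM library 2. AXIN2, a WNT target named after its values were seen, fell by 2.01 on the log2 scale. It may be that DPM lowers WNT signalling in the cells, that the share of mesenchymal cells is lower, or that particles take up CHIR99021 or growth factors from the medium, and the first and last of these were not tested, for which CHIR99021 could be measured in medium after contact with particles, or WNT targets in organoids given such medium freed of particles.

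Control library 2 held transcripts of muscle, of which ACTC1 at 66.7 FPKM and TNNI1 at 30.4 were seen first, against 0.38 and 1.22 in control library 1. ERM libraries 1 and 2 were listed at 2507 and 2397 FPKM for ACTC1 and 3226 and 3295 for TNNI1. Both genes are among the 485 rows whose ERM values may not belong to their genes. In a separate list of muscle genes, 8 of the 12 detected genes were over 4-fold higher in control library 2 than in each of control library 1 and both DPM libraries, among them MYH3 (31.4 FPKM), MYL4 (23.0), DES (13.9) and MYOG (8.17). This may come from a small muscle-like cell population in that sample. DES is also on the mesenchymal list. None of the 8 muscle genes tested in DPM vs control passed the threshold. They are not the same 8 genes, since TNNC1, TNNI3 and MYL3 passed the filter but were not over 4-fold higher in control library 2. A gene high in only 1 of the 2 control libraries varies widely within its group, so this does not show that the comparison was unaffected. The labels give no difference between the 2 control samples, so what would have given rise to such cells was not tested.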
